A study of Mus musculus with 6 samples.

How the data were processed

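RNA of KPC1199 cells, a mouse cell line that the labels describe as pancreatic tumour cells, was sequenced in 6 libraries, 3 labelled WT and 3 labelled ACSL5 knockdown. Per the labels, total RNA was extracted with TRIzol and the libraries were sequenced on an Illumina platform. The titles of the knockdown libraries say KO and their genotype field says knockdown. The library names begin with siACSL5 in both groups, followed by CY3 for WT and 2260 for knockdown, and the labels do not say what these additions stand for. No label says whether the 3 libraries of a group come from separate cultures, so every p-value measures the spread between libraries, which may be partly technical. Strandedness and the program that quantified the genes are not given in the sources used here.

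The submitters' processing notes name fastp, HISAT2, StringTie and DESeq2, without versions or roles. The notes name the human genome builds hg38 and GRCh38, while the gene identifiers are those of mouse. The authors deposited a table of expected counts per gene and library, in which between 10.1% and 13.0% of the values in a library were not whole numbers. A second table, deposited by the authors, gives TPM, the share of transcripts scaled to a fixed sum, and its library columns sum to between 999999 and 1000001. Each table also has columns that equal the group means, which were not used. Each table holds 57508 genes, of which 56980 carry a mouse Ensembl identifier and 528 are loci assembled from reads. The authors' table also gives a length in bases for each gene.

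Library totals lay between 21794201 and 29996160 expected counts. Counts were rounded to whole numbers. Genes were filtered with filterByExpr on the 2 groups, libraries were scaled by TMM, and groups were compared with the quasi-likelihood F test of edgeR 4.0.16, with robust estimation, in R 4.3.3. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p below 0.05. The Acsl5 level was also compared by an exact permutation test over the 20 assignments of the libraries. Levels are given as CPM scaled by TMM, and log2 fold changes are ACSL5 knockdown minus WT.

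A total of 41 gene lists were written down before the data were examined. They cover lipid metabolism, stress, central metabolism, proliferation, tumour state, signalling and markers of other cell types. The 37 lists with at least 5 tested members were compared with all other genes by camera of limma 3.58.1, with a preset correlation of 0.01. Calls were repeated with a correlation estimated for each list and with fry, which tests whether the genes of a list move, on balance, one way. Benjamini-Hochberg adjustment was over the 37 lists.

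Genes are named by a rule written before the data were examined. It takes Acsl5 and the other Acsl genes. It takes the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 5 CPM, a gene symbol that is not a predicted name, and all knockdown libraries on one side of all WT libraries. It takes the 5 higher and the 5 lower of these with the smallest p. It takes up to 4 members of each called list, with the strongest member moving against it, and up to 2 members of each other list. Any other gene named below was chosen after its values were seen. The rule was applied to the fit without WT replicate 1, since the fit of the 6 libraries called no gene. Leaving out each library had been chosen in advance, and the use of this fit as the place where genes are named was chosen after the data were examined.

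Alternatives written down before the data were examined were size factors of DESeq2, library totals without a composition factor, no filter, and a filter of 1 CPM in every library of a group. Further ones were DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1) and log2(TPM + 0.1) for genes with a mean of at least 1 TPM in a group, a fit without robust estimation, and a threshold of 0.01. The replicate number as a block, and leaving out each library, completed them. Added after the data were examined were quality weights per library in limma-voom, the removal of each library's smooth trend with gene length or GC content (lowess, span 0.3), and the same alternatives for the fit of 5 libraries. A fit without genes that hold a 7-base site in the 3' UTR and list tests with Acsl5 left out of the lists were also added.

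Gene positions, GC content and 3' UTRs were taken from GENCODE M21 on GRCm38. GC content was known for 96.3% of the 15152 genes tested without WT replicate 1. Log2 fold changes were taken for 10929 genes with an annotated 3' UTR of at least 50 bases and a mean log2 CPM above 1. They were adjusted by regression for length, GC, CpG and A content of the UTR and for length, GC content and exon number of the transcript. The remainders were compared between genes with and without each of 16137 sequences of 7 bases (7-mers). Each sequence was found in at least 50 of these UTRs but not in most of them. Scores are given with the GC trend removed, except against a single WT library. The difference was scaled to a score over all sequences. These steps used Python 3.11.15 with pandas 2.3.3 and NumPy 2.4.6.

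The fits were tested on simulated data with the spread of the real libraries, in which 50 genes were changed by each of 4 fold sizes. With the spread of the 6 libraries, edgeR called 34 of the 50 genes changed 4-fold, 0 of the 50 changed 2-fold and 5 unchanged genes. With the spread of the 5 libraries it called 47 of 50 at 4-fold, 40 at 2-fold, 37 at 1.5-fold and 10 at 1.25-fold, beside 20 unchanged genes. A simulated list shifted by 0.5 on the log2 scale was called by camera, by camera with an estimated correlation and by fry, each with 0 other lists. The simulated genes varied independently, so this does not show how the list tests behave where members of a list vary together.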

Results

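Expression was measured by RNA sequencing in 6 libraries of KPC1199 mouse pancreatic tumour cells. There were 3 WT and 3 ACSL5 knockdown libraries. Expected counts totalled 21794201, 21993901 and 29996160 in WT replicates 1, 2 and 3, and 23095334, 26047445 and 25925719 in knockdown replicates 1, 2 and 3. The number of genes with a value above 0 ranged from 19800 to 21698 per library. The comparison of the groups addresses what ACSL5 does as pancreatic ductal adenocarcinoma progresses, which the series design gives as its purpose.

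Acsl5, which encodes a long-chain acyl-CoA synthetase that activates fatty acids with coenzyme A, was lower in each of the 3 knockdown libraries than in any WT library. Its level was 342.4, 265.2 and 270.2 CPM in WT replicates 1, 2 and 3, and 49.8, 55.6 and 57.2 CPM in knockdown replicates 1, 2 and 3. The means were 292.6 ± 43.2 CPM (SD, n = 3) in WT and 54.2 ± 3.91 CPM (SD, n = 3) in knockdown cells, which left 18.5% of the WT level. Acsl5 (ENSMUSG00000024981) lies on chromosome 19 of GRCm38, from 55251938 to 55297720 on the plus strand, and its annotated transcript of 4243 bases has 22 exons. The two-sided exact permutation test gave p = 0.1, the smallest that 3 libraries against 3 allow.

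**Figure D1:**
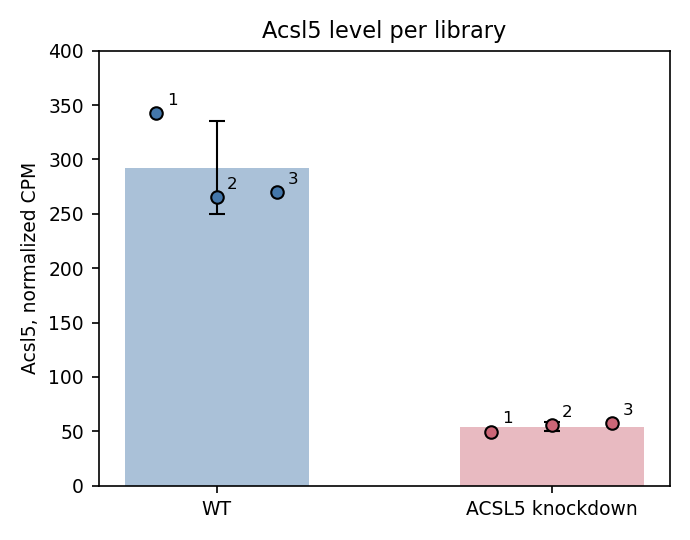
Acsl5 level in normalized CPM (y axis) for the WT and ACSL5 knockdown groups (x axis). Bars are group means, error bars the SD (n = 3), and points single libraries with their replicate number. The knockdown libraries lie between 49.8 and 57.2 CPM and the WT libraries between 265.2 and 342.4 CPM.

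Over the 6 libraries, the log2 fold change of Acsl5 was -2.43 (SE 0.167), and it ranked first of 14679 genes tested. Its adjusted p in edgeR was 0.0619, above the threshold, and the adjusted p was 2.97e-32 in DESeq2 and 5.95e-08 in edgeR without WT replicate 1. No gene was called over the 6 libraries in edgeR (0 of 14679), while 2351 genes had an unadjusted p below 0.05, where chance alone gives 734. DESeq2 called 724 genes, limma-voom 8, and limma-trend on log2(TPM + 1) 0.

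At the level of gene lists, 8 of 37 were called over the 6 libraries. Transcripts of the mitochondrial genome (median log2 fold change -0.82, adjusted p = 5.69e-05), nuclear-encoded genes of oxidative phosphorylation (-0.56, adjusted p = 0.00418), tricarboxylic acid cycle genes (-0.34, adjusted p = 0.0376) and ferroptosis regulators (-0.26, adjusted p = 0.0371) were shifted down. ERK/AP-1 immediate early genes (0.44, adjusted p = 0.00308), targets of MYC and ribosome biogenesis (0.13, adjusted p = 0.0187), extracellular matrix genes (0.32, adjusted p = 0.0371) and YAP/TEAD targets (0.27, adjusted p = 0.0376) were shifted up. None of the 8 lists was called with an estimated correlation (lowest adjusted p = 0.596 with an estimated correlation). Of these lists, 3 were also called without WT replicate 1, namely the mitochondrially encoded transcripts, the ERK/AP-1 genes and the MYC list.

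WT replicate 1 stood apart from the other 5 libraries. Its log2 CPM values had a Pearson correlation across genes of 0.847 to 0.876 with the other libraries, whose 10 pairs ranged from 0.963 to 0.996 (genes are not independent replicates). Ribosomal protein genes took 9.74% of its counts and 3.71% to 4.37% of those of the other 5 libraries. Compared with the mean of the other libraries, the shortest 10% of 11859 genes was higher in it by a median of 0.93 on the log2 scale and the longest 10% was at -1.32. The median differences of the other 5 libraries lay between -0.28 and 0.32 in these genes. The genes of oxidative phosphorylation had a median log2 fold change of -0.56 with WT replicate 1 and 0.01 without it (adjusted p = 0.525).

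**Figure D2:**
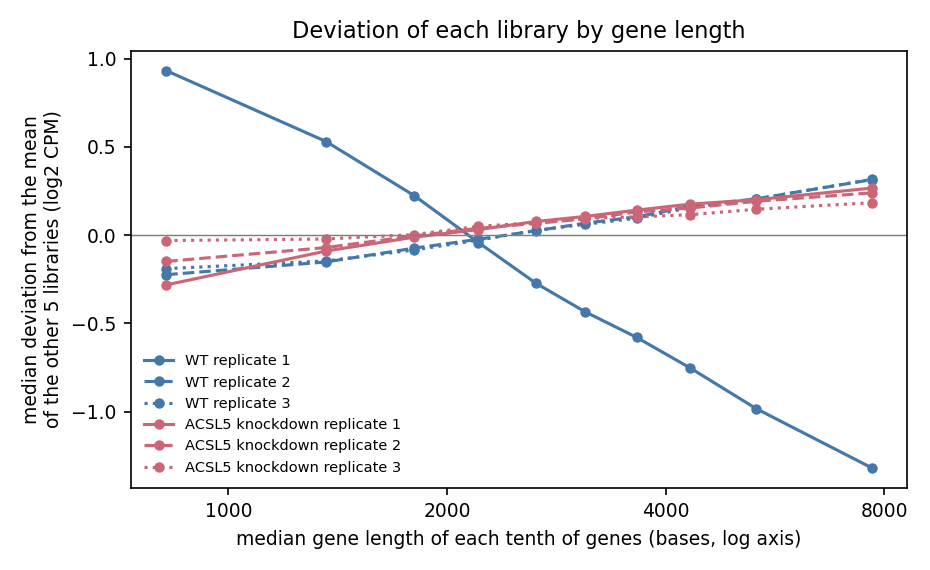
Median deviation of each library from the mean of the other 5 libraries, in log2 CPM (y axis), for 10 groups of genes ordered by length (x axis, median length in bases on a log axis). Lines are libraries, coloured by group. WT replicate 1 falls from 0.93 in the shortest genes to -1.32 in the longest.

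Without WT replicate 1, knockdown cells differed from WT replicates 2 and 3 in many genes beside Acsl5, mostly by less than 1 log2 unit. Higher genes included the inducible chaperones Hspa1a and Hspa1b and the stress-responsive cytokine Gdf15. Lower genes included Ugdh, which makes UDP-glucuronate, the splicing factor Srsf9, the translation repressor Eif4ebp2, transcripts of the mitochondrial genome and several hypoxia-responsive genes. In all, 5193 of 15152 genes were called, 2471 higher and 2722 lower, of which 480 differed by at least 1 log2 unit. The balance depends on the scaling, with 2864 higher and 2356 lower under library totals, and 1459 higher and 1008 lower with log2(TPM + 1). The count was 3124 when WT replicate 2 was left out too and 2599 when WT replicate 3 was, where the lone WT library is assumed to vary like the knockdown libraries. The log2 fold changes followed GC content (Spearman 0.328 across genes), with a median of -0.15 in the 10% of genes with the lowest GC content and 0.33 in the 10% with the highest. After removal of this trend in each library, 4748 genes were called, and 3796 of the 5193 were called again in the same direction.

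Among the genes with the largest changes, Hspa1b rose from 7.49 ± 1.88 CPM (SD, n = 2) to 81.8 ± 41.4 CPM (SD, n = 3), and Hspa1a from 2.58 ± 0.245 to 22.9 ± 8.64 CPM. These genes are close paralogs that share reads. Gdf15 rose from 4.79 ± 1.44 to 41.5 ± 17.8 CPM, a log2 fold change of 3.12 (SE 0.558, adjusted p = 0.0296). Knockdown replicate 1 was the highest for Hspa1b (129.2 CPM, against 52.6 and 63.6 in replicates 2 and 3) and for Gdf15 (61.8, against 28.8 and 33.9). The tubulin polyglutamylase subunit gene Tpgs1 rose by 3.33 on the log2 scale, Cfap43 of cilia and flagella by 2.06 and Fam43a by 1.87. A further 3 genes of mitochondrial proteins also rose, Bola1 by 2.19, Romo1 by 2.11 and the complex I assembly factor gene Ndufaf8 by 2.03. The pseudogene Rps13-ps1 had the highest value, 3.85, and shares sequence with the ribosomal protein gene it is named for. By smallest p, the higher genes were Irs2, which encodes an insulin receptor substrate (1.56, SE 0.0713), the matrix proteoglycan gene Prelp (1.28), the metallothionein gene Mt2 (1.48), Selenoh (1.81) and the macrophage growth factor gene Csf1 (0.94).

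Of the lower genes, Ugdh fell from 308.1 ± 0.574 CPM (SD, n = 2) to 119.7 ± 2.29 CPM (SD, n = 3), a log2 fold change of -1.38 (SE 0.0433, adjusted p = 6.62e-08). Srsf9 fell from 57.9 ± 1.42 to 18.01 ± 0.470 CPM, a log2 fold change of -1.70. Eif4ebp2 fell from 108.9 ± 2.77 to 42.3 ± 3.91 CPM, a log2 fold change of -1.38. The aldehyde dehydrogenase gene Aldh1a7 was at -1.71, Rida at -1.79, Klhl1 at -1.62, Rnf141 at -1.45, Golm2 at -1.39 and the pseudogene Idi1-ps1 at -1.43. By smallest p, the list also held Ero1a, an oxidase of the endoplasmic reticulum (-1.16), and Cyb5b, a cytochrome b5 of the outer mitochondrial membrane (-1.05). The 7-base sequence GAACTAC, which occurs in the coding sequence of Acsl5, or the related AACTACA was present in the 3' UTRs of Ugdh, Srsf9, Eif4ebp2, Rnf141, Golm2, Aldh1a7, Ero1a and Cyb5b. Of the other lower genes, Rida had no site, Klhl1 had only 6 bases of it, and Idi1-ps1 was not searched. The sequence was found from these same fold changes.

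**Figure D3:**
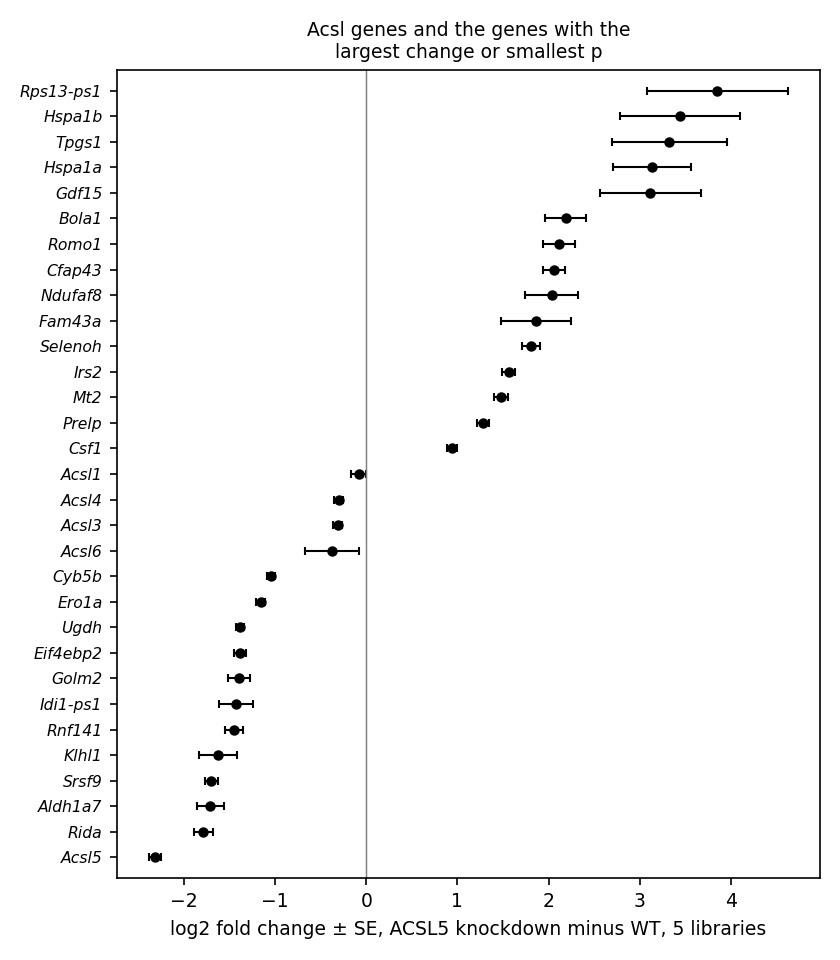
Log2 fold change, ACSL5 knockdown minus WT, over 5 libraries (x axis) for the Acsl genes and the genes named by their change or p (y axis). Points are estimates and bars their SE. Acsl5 is lowest at -2.32 and Rps13-ps1 highest at 3.85.

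The other Acsl genes moved little. Acsl3 and Acsl4, which also activate long-chain fatty acids, were at -0.31 (SE 0.0501, adjusted p = 9.2e-04) and -0.30 (SE 0.0464, adjusted p = 7.21e-04) without WT replicate 1. With the GC trend removed they were at -0.18 and -0.15, both still called. Over the 6 libraries neither was called, and there both had a positive sign with deposited TPM values. Without WT replicate 1 both kept their negative sign with TPM values. Acsl1 was at -0.08 (adjusted p = 0.503) and at 0.16 over the 6 libraries, and Acsl6, below 2 CPM, at -0.37 (adjusted p = 0.371).

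None of the 8 lists of lipid metabolism was called by camera in the fit without WT replicate 1. Fry called 5 of them in this fit, namely acyl-CoA synthetases (down, adjusted p = 0.00931), phospholipid synthesis (down, 0.0116), PPAR targets (up, 0.0141), fatty acid synthesis (down, 0.0264) and cholesterol synthesis (down, 0.0265). In 13 alternative settings of this fit, each with camera, acyl-CoA synthetases were called down in 7 and PPAR targets up in 1. Among acyl-CoA synthetases, 4 of 14 tested members fell, Acsl5 itself among them, and 1 rose (adjusted p = 0.0769 for the list). In this fit, with the GC trend left in, the list had a median of 0.002 and a mean of -0.17, and so differed in sign between the median and the test. Without Acsl5, the other 13 members had a mean of -0.004 and adjusted p = 0.969. Fatty acid oxidation had 12 lower and 4 higher of 36 members (adjusted p = 0.243), with the enoyl-CoA hydratase gene Echs1 at -0.81 and Acads at -0.50. In fatty acid synthesis, elongation and desaturation, 6 of 25 fell and 4 rose (adjusted p = 0.377), with the desaturase gene Scd1 at -0.46 and the elongase gene Elovl6 at -0.40. Cholesterol synthesis and uptake had 10 lower and 6 higher of 26 (adjusted p = 0.361), with Hmgcs1 at -0.43. For triacylglycerol synthesis and lipid droplets the counts were 6 lower and 7 higher of 26 (adjusted p = 0.928), with Plin2, which coats lipid droplets, at 0.36 and Fitm2 at -0.44. This list had 8 lower and 3 higher with the GC trend removed, fatty acid oxidation 7 and 3, and fatty acid synthesis, elongation and desaturation 8 and 2. In that fit cholesterol synthesis and uptake had 6 lower and 3 higher, and phospholipid synthesis and remodelling 7 and 1. Phospholipid synthesis and remodelling had 8 lower and 3 higher of 29 (adjusted p = 0.361), with Mboat2 at -0.62 and Lpcat3 at -0.43. PPAR targets had 6 higher and 2 lower of 18 (adjusted p = 0.113), with Vnn1 at 1.45 and Angptl4 at 0.63. Cholesterol efflux and LXR targets had 4 higher and 3 lower of 11 (adjusted p = 0.392), with Apoe at 1.63 and below 3 CPM. With the GC trend removed, the acyl-CoA synthetases (down, adjusted p = 0.0412) and the PPAR targets (up, adjusted p = 0.0438) passed the threshold, both with adjusted p = 0.432 with an estimated correlation. Acsl5 carried the first of these calls, since the other 13 synthetases gave adjusted p = 0.876 with the GC trend removed.

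Of 36 genes of MYC and ribosome biogenesis, 26 rose, 1 fell and 9 were not called (28 higher and 2 lower adjusted over the list alone), with a median of 0.25. Adjusted p was 4.12e-08 with the preset correlation and 0.329 with an estimated correlation. Nhp2, a core protein of H/ACA ribonucleoproteins, was at 0.98, Myc itself at 0.79, Ppan at 0.69 and the ornithine decarboxylase gene Odc1 at 0.58, while the nucleolar Npm1 was at -0.39. With all 6 libraries Nhp2 was at 0.05 (adjusted p = 0.967) and Myc at 0.49 (adjusted p = 0.385). The 13 protein-coding transcripts of the mitochondrial genome all had a negative sign, and 7 were called lower and 0 higher (the same counts adjusted over the list alone), with a median of -0.55 and adjusted p = 3.34e-06 (0.487 with an estimated correlation). With the GC trend removed the median was -0.36 and 1 of the 13 had a positive sign. In this list mt-Nd4 was at -0.63, mt-Nd5 at -0.61, mt-Nd2 at -0.58 and mt-Co1 at -0.42, although copies of the mitochondrial sequence in the nuclear genome share reads with some of these. All mitochondrially encoded genes took 3.28% to 3.32% of the counts in the 3 WT libraries, replicate 1 included, and 2.42% to 2.53% in the 3 knockdown libraries.

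Of the 29 ERK/AP-1 immediate early genes, 14 rose and 5 fell (14 and 5 adjusted over the list alone), with a median of 0.40 and adjusted p = 0.00868 (0.694 with an estimated correlation). Dusp1, a phosphatase of MAP kinases, was at 1.27, and Jun at 1.42, Fosb at 1.21 and Ier2 at 1.05 were chosen after their values were seen. Members against the list were the transcription factor genes Etv5 (-0.84) and Etv4 (-0.64), both targets of ERK signalling. Etv5 has a 7-base site in the 3' UTR and Etv4 has none. Of 24 hypoxia-response genes, 10 fell and 3 rose (12 and 3 adjusted over the list alone), with a median of -0.18 and adjusted p = 0.00868 (0.487 with an estimated correlation). Its median was -0.10 with the GC trend removed, and -0.07 with all 6 libraries (adjusted p = 0.145). Lower members included Ero1a, the pyruvate dehydrogenase kinase gene Pdk1 (-0.87), the mitophagy receptor gene Bnip3 (-0.64) and Epas1 (-0.68), which encodes HIF-2 alpha, while the demethylase gene Kdm3a rose by 0.30. The hypoxia list lost its call without the genes that have a 7-base site in the 3' UTR (adjusted p = 0.187), 3 of the 10 lower members being such genes. Antigen presentation by MHC class I had 6 of 19 members higher and 0 lower (5 and 0 adjusted over the list alone), with a median of 0.25 and adjusted p = 0.0225 (0.487 with an estimated correlation). With all 6 libraries its median was 0.02 (adjusted p = 0.338). The peptide transporter gene Tap2 was at 1.08, H2-Q4 at 0.72, Tapbp at 0.66 and H2-D1 at 0.45, where the H2 genes share reads with one another. The MHC list was called in 11 of the 13 settings, and not with the stricter filter (adjusted p = 0.071) or with the GC and length trends removed (adjusted p = 0.0518).

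**Figure D4:**
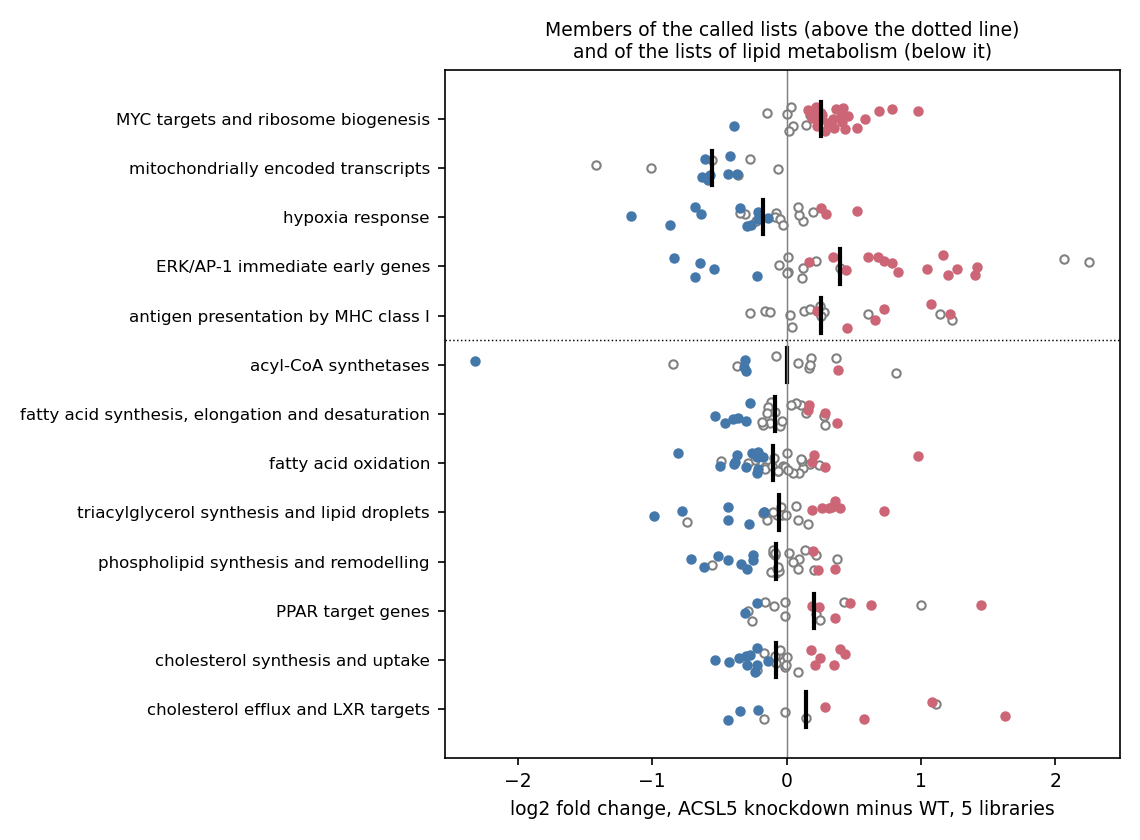
Log2 fold change, ACSL5 knockdown minus WT, over 5 libraries (x axis) of each tested member of the called lists and of the lists of lipid metabolism (y axis). Filled points are genes called higher (red) or lower (blue), open points genes not called, and black bars list medians. The list of MYC and ribosome biogenesis has 26 filled points above 0, and the mitochondrially encoded transcripts have 7 below 0.

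None of these 5 lists was called with an estimated correlation, and fry called 4 of them, without the ERK/AP-1 list (adjusted p = 0.0965). The estimated correlation was 0.0101 for the MYC list and -0.0394 for the MHC list, near or below the preset 0.01. A larger correlation between members thus does not account for the loss of the MYC and MHC calls. The other estimates were 0.0169 for hypoxia, 0.295 for the mitochondrially encoded transcripts and 0.369 for the ERK/AP-1 list. With the preset correlation all 5 stayed called with the GC trend removed, with adjusted p from 2.26e-08 to 0.0423. With the GC and length trends removed, the ERK/AP-1 list was called (adjusted p = 0.0457) and the MHC list was not (adjusted p = 0.0518). With Acsl5 also left out of the lists, neither the ERK/AP-1 list (adjusted p = 0.0534) nor the MHC list (adjusted p = 0.0583) was called. Acsl5 is a member of neither, so this last change comes only from the adjustment over the lists.

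Many of the named values depend on the libraries fitted. With all 6 libraries the log2 fold changes were smaller, by more than 1.5-fold, for Scd1 (-0.22), Plin2 (0.16), Angptl4 (0.39), Acsl4 (-0.15), Odc1 (0.36), H2-D1 (0.14), H2-Q4 (0.40) and Tapbp (0.38). They were larger for Npm1 (-0.72), Kdm3a (0.52) and mt-Nd5 (-0.97), and none of these was called there. With the GC trend removed, Ppan was at 0.39, Npm1 at -0.25, mt-Co1 at -0.27 and Acads at -0.81, all still called.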

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

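The quality weights, the removal of trends, the fit without 7-mer sites, the lists without Acsl5 and all alternatives of the 5-library fit were chosen after the data were examined. Over the 6 libraries, the count of 0 genes became 1 with library totals, 4 without a filter, 724 in DESeq2 (376 higher, 348 lower), 8 in limma-voom, 5 without robust estimation and 5937 with quality weights. It became 938 with the length trend removed, 601 with the length and GC trends removed and 5193 without WT replicate 1 (range 0 to 5193 when each library was left out). The quality weight of WT replicate 1 was 0.0312, against 0.964 to 2.53 for the other libraries. The weighted fit thus nearly leaves that library out and is no separate support for the count without it. The log2 fold change of Acsl5 kept its sign in every alternative. It passed the threshold at -2.31 with library totals (adjusted p = 0.0348), -2.40 without a filter (0.0164), -2.44 in DESeq2 (2.97e-32) and -2.43 in limma-voom (0.0217). It also passed at -2.28 with quality weights (2.91e-09), -2.60 with the length trend removed (0.0110), -2.55 with both trends removed (0.0139) and -2.32 without WT replicate 1. Leaving out each library gave -2.50 to -2.32, and the adjusted p reached 0.486, against 0.438 with the replicate block. The 8 lists were 12 without a filter (7 up, 5 down), and library totals left 5, the length trend removed 3, both trends removed 2, an estimated correlation 0 and fry with the replicate block 0. Fry called 4 others, and leaving out each library gave 5 to 8 lists.

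Without WT replicate 1, the 5193 genes were 0 with all 6 libraries, 2467 with log2(TPM + 1) (1459 higher, 1008 lower), 2569 with log2(TPM + 0.1) (1549 higher, 1020 lower) and 3217 at 0.01. Leaving out a further library gave 2599 to 6188, with 3124 without WT replicate 2 and 2599 without WT replicate 3, where fewer samples were fitted. Lists called numbered 5, against 8 with all 6 libraries (3 of the 5 among them), 9 with the GC trend removed (5), 8 with this and Acsl5 left out of the lists (5), 0 with an estimated correlation, 17 with fry (4) and 2 with fry and the block over replicates 2 and 3 (0 of the 5). Leaving out a further library gave 5 to 7 lists. Library totals gave 5220 genes (2864 higher, 2356 lower), and all other alternatives gave 4351 to 5730 genes and 4 to 7 lists. Deviations from the group means of libraries of the same number had correlations of -0.116, 0.0444 and -0.194 across genes. This check cannot tell whether replicate numbers pair the libraries, since WT replicate 1, which stood apart, shapes the WT mean and so every WT deviation. TPM values moved the median log2 fold change of all genes by 0.26 with a pseudocount of 1 and 0.30 with 0.1 over the 6 libraries, and library totals by 0.08.

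Of the named genes, 7 values over the 6 libraries and 3 without WT replicate 1 changed sign, none of them past the threshold. Acsl1 ranged from -0.0795 without WT replicate 1 to 0.326 without WT replicate 2, and was at -0.0263 with quality weights and 0.163 with all 6 libraries. With TPM over the 6 libraries, Acsl3 was at 0.02 with both pseudocounts (0.0151 and 0.0165) and Acsl4 at 0.16 and 0.17. Acsl6 ranged from -0.373 without WT replicate 1 to 0.0685 without WT replicate 2. With all 6 libraries Ndufa6 was at -0.0678 and Ago1 at 0.0258. The rest kept their direction, 405 on the same side of the threshold and 144 newly past it over the 6 libraries, and 1758 on the same side and 158 no longer past it without WT replicate 1. Apart from the constructions named, the cause was not tested. Depth does not limit Acsl5, with 1186 to 8324 expected counts per library.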

Other observations

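Tests of the length trend, of the Acsl5 level in WT replicate 1 and of the GC trend as the whole cause, with the use of the fit without WT replicate 1 to name genes, were chosen only after the result was seen. None of the other lists was called by camera in the fit without WT replicate 1, and each is given here with its numbers of members called higher and lower in that fit. Fry called 8 of them in this fit: ferroptosis regulators (down, adjusted p = 0.00614), heat shock (up, 0.0181), ATF4 targets (up, 0.0264), glycolysis (down, 0.0264), apoptosis regulators (down, 0.0312), the basal-like subtype (down, 0.0312), the tricarboxylic acid cycle (down, 0.0410) and mesenchymal genes (up, 0.0425). In the 13 alternative settings with camera, heat shock genes were called up in 5, glycolysis down in 2 and ferroptosis regulators down in 2. With an estimated correlation and no other alternative, adjusted p was 0.487 for heat shock, 0.687 for glycolysis and 0.487 for ferroptosis. With the GC trend removed, adjusted p was 0.0412 for heat shock and 0.0182 for glycolysis (0.432 for both with an estimated correlation). With GC and length removed it was 0.0457 and 0.00971 (0.416 for both with an estimated correlation), and heat shock lost its call there with Acsl5 left out of the lists (0.0534). Acsl5 is not a member of the heat shock list, so that loss comes only from the adjustment over the lists. Among stress lists, heat shock genes had 7 of 17 higher and 1 lower (adjusted p = 0.113), with Bag3 at 0.47 and Hspa4l at -0.37. ATF4 targets had 12 higher and 12 lower of 41, with Gdf15, Ppp1r15a (0.87) and Slc3a2 (0.84) higher. Targets of ATF6 and XBP1 had 7 and 7 of 29, with Calr at -0.60. NRF2 targets had 4 higher and 8 lower of 25, with Txnrd1 at -0.76 and Tkt at -0.41. Calr, Txnrd1 and Tkt have a 7-base site in the 3' UTR. Of the other list members named as lower in this report, so do Pdk1, Fitm2, Bak1, Slc16a1, Hspa4l, Wipi1, Egfr, Tgfbr1, F3 and Pdgfra. Others have none, such as Slc40a1, Zmat3, Aco1, Cs, Bub1, Agr2 and Areg. Ferroptosis regulators had 3 higher and 8 lower of 21 (adjusted p = 0.0769), with the iron exporter gene Slc40a1 at -1.15 and Ptgs2 at 0.69. Targets of p53 had 6 higher and 7 lower of 27 (Plk2 0.87, Zmat3 -0.55), and apoptosis regulators 4 and 8 of 29 (Casp6 -0.77, Bak1 -0.47). In central metabolism, glycolysis had 5 higher and 8 lower of 25 (Slc16a1 -0.63), the tricarboxylic acid cycle 4 and 11 of 25 (Aco1 -0.49, Cs -0.48), and autophagy and lysosome 7 and 9 of 37 (Gabarapl1 0.63, Wipi1 -0.56). Nuclear-encoded oxidative phosphorylation had 9 and 5 of 57 (Ndufs7 0.76, Ndufa6 0.47).

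Proliferation lists had members on both sides. G1/S and DNA replication had 8 higher and 8 lower of 40, with Cdt1 at 1.07 and Pold1 at 0.59, and G2/M and mitosis had 10 and 8 of 40, with the checkpoint kinase gene Bub1 at -0.77 and Ccna2 at -0.40. Markers of tumour state were mixed too. Mesenchymal genes had 10 higher and 4 lower of 25 (Thbs1 0.67, Spp1 -0.44), epithelial genes 5 and 5 of 23 (Cdh1 0.42, Krt7 0.49) and matrix genes 10 and 8 of 29 (Col18a1 -0.53, Lamb1 -0.38). The classical subtype of pancreatic cancer had 5 higher and 4 lower of 22 (Agr2 -1.33), and the basal-like subtype 1 and 3 of 12 (Areg -1.12, Egfr -0.89). In signalling, TGF-beta targets had 7 and 7 of 22 (Smad7 0.99, Tgfbr1 -0.56), YAP/TEAD targets 10 and 5 of 23 (Amotl2 1.32, F3 -0.96), and NF-kB targets 9 and 6 of 33 (Csf1 0.94). The type I interferon response, which transfected RNA can raise, had 5 higher and 5 lower of 33 (Bst2 1.27, Eif2ak2 -0.26), and small RNA machinery 1 and 2 of 12 (Tnrc6c 0.41, Ago1 -0.34). Fibroblast markers had 2 and 2 of 7 (Pdgfra -0.62, Pdgfrb 0.73). With the GC trend removed the counts of higher and lower members were 14 and 2 for G2/M and mitosis, the 2 lower ones being Bub1 and Ccna2. Adjusted p for this list was 0.189 with camera, 0.546 with an estimated correlation and 0.00680 (up) with fry. The counts were 7 and 13 for the matrix genes (adjusted p = 0.257 with camera), 7 and 6 for mesenchymal and 4 and 8 for epithelial genes. In that fit Pold1 was at 0.23, Hspa4l at -0.22, Ndufs7 at 0.47, Col18a1 at -0.88 and Eif2ak2, no longer called, at -0.13 (adjusted p = 0.0596). With all 6 libraries the values were smaller by more than 1.5-fold for Slc3a2 (0.49), Hspa4l (-0.13), Ndufs7 (0.48), Krt7 (0.20), Col18a1 (-0.19), Lamb1 (-0.24), Egfr (-0.57), Tgfbr1 (-0.24), Bst2 (0.76), Eif2ak2 (-0.11) and Pdgfra (-0.36). They were larger for Calr (-0.90), Thbs1 (1.01) and Tnrc6c (0.71), of other sign for Ndufa6 and Ago1, and none of these was called there. The list test differed in sign from the median for the targets of ATF6 and XBP1, G2/M and mitosis, the matrix genes and both subtypes. It differed from the mean for the targets of ATF6 and XBP1, G1/S and DNA replication, both subtypes and the fibroblast markers.

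The first pattern is that 0 genes were called over the 6 libraries. WT replicate 1 is argued against as a knockdown library, since its Acsl5 level was 5.98 times that of the highest knockdown library. Cells of another type are argued against by their markers: among lists of at least 50 CPM the highest ratio to the other WT libraries was 1.47, for leukocyte markers (88.0 CPM, of which Cd14 82.7), with 0.71 for fibroblast markers. The endothelial (1.26, 13.8 CPM), acinar (2.04, 15.1 CPM) and islet markers (2.09, 0.546 CPM) lay below 50 CPM. The gene length trend of this library may account for part of the missing calls, since its removal raised the count to 938, while 5193 were called without the library, and why its short genes are higher, for instance RNA quality or library preparation, stays open.

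The second pattern is that the genes called without WT replicate 1 follow GC content. A GC trend as the whole cause is argued against, since 73.1% of the 5193 genes were called again in the same direction with the trend removed, although a first bound of 75% was narrowly missed and the bound of 50% was set after this value was seen. Of the 1390 genes called only with the trend left in 98.2% follow its direction, but these genes were chosen because its removal ended their call, so the share is fixed by the choice and decides nothing. Whether the trend comes from the libraries or from the knockdown stays open, since the 5 libraries fitted carry it by group (Spearman -0.288 and -0.406 in WT, 0.235 to 0.371 in knockdown), while WT replicate 1 does not carry it when set against all other libraries (0.013). The log2 fold changes also followed exon number (Spearman -0.125, and -0.155 with the GC trend removed), and this second trend was not removed.

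The third pattern concerns the lower genes and is a hypothesis: the siRNA may have acted on other mRNAs through its seed, the bases that pair with 3' UTRs. The 7-mer GAACTAC had the lowest score of 16137, -14.21 (601 genes), lies in the Acsl5 mRNA, as do 3475 of the 16137, and was followed by AACTACA at -9.48, while the highest score was 3.95. It was also lowest against WT replicate 1 alone (-7.909, GC trend left in), which argues against WT replicates 2 and 3 as its source. Of 406 other 7-mers of the same bases, without those that share a longer run of bases with it, 0% passed the bound of -4.5. The low score was not shared by these 7-mers. This is no separate test of base composition, since the scores were already adjusted for the composition of the UTRs. Of genes with the 8-mer GAACTACA 55.0% were called lower and 6.15% higher, against 18.6% and 22.4% without a site. These are shares of the same data in which the sequence was found, with the GC trend left in and UTR length not adjusted for. The 8-mer genes had a median log2 fold change of -0.26, and -0.20 with the GC trend removed, against 0.02 in both fits without a site. Genes with only AACTACA had a median of -0.11, and -0.04 with the GC trend removed. However, 7-mer or 8-mer sites cover only 572 of 2465 lower genes searched (23.2%), against 12.45% of all genes searched and 6.29% of higher genes. Among genes lower by at least 1 log2 unit, 35 of 70 had a site. These shares also come from the data in which the sequence was found. Smad7 and Amotl2 rose despite a site. GAACTAC occurs in exons 9 and 16 of Acsl5, and a 21-base target ending 1 base after the latter (bases 2273 to 2279 of the annotated mRNA) would start at the base whose number the knockdown library names carry, but the labels do not say what that number means, the guide sequence is not given in the sources used here, and effects of lower Acsl5 stay open.

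Other splits of the libraries were counted. Over the 6 libraries, 10 of the 10 splits called as many genes as the real one (0, highest other 0), and 1 of 10 called as many lists (8, highest other 7). Over the 5 libraries, 1 of 10 splits gave as many genes (5193, highest other 0). The real split of these libraries called 5 lists, and the split of knockdown replicates 1 and 2 from the rest called 4. With 10 splits no share can fall below 0.05. Every other split also puts WT and knockdown libraries together in a group, so a difference between WT and knockdown adds to its spread and lowers its count of genes. The low counts of the other splits therefore decide nothing.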
